A study of Mus musculus with 3 samples.

How the data were processed

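RNA from ovulated mouse oocytes of 3 litters was sequenced, with 1 library per litter and no second group of samples. Per the labels, the females had been superovulated, the eggs were collected by embryonic day 0.5, and total RNA from lysed oocytes was copied by single primer isothermal amplification with a commercial kit before Illumina libraries were built. In this amplification, cDNA made from the RNA is copied linearly at a constant temperature. The females carried floxed alleles of Kdm1a, the gene of the histone demethylase LSD1, without the oocyte-specific Cre transgene that would delete it, and so serve as wild type per the labels.

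The authors deposited 1 coverage track per library, in which each value is the number of alignments over every base of an interval, not scaled to sequencing depth. Per the submitters' processing notes, reads were aligned with Bowtie to mm9; the version, the number of placements allowed per read and any filter are not given in the sources used here. Per the file headers, each track was made from the sorted alignments of 1 lane, namely lane 3 for litter 1, lane 4 for litter 2 and lane 8 for litter 3. Strand, mapping quality and read identity are not part of such a track.

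The deposited coverage was turned back into alignment counts. Isolated blocks at a depth of 1 were multiples of 72 bases long in 100% of cases, and 99.9% of them were exactly 72 bases, so every alignment was taken as 72 gapless bases. The number of alignments that start at a base is then the step in depth at that base plus the number that start 72 bases earlier. This gave 0 negative values and 0 gaps in the tiling in each of the 3 libraries, and totals that equal the summed depth divided by 72. Simulated reads on a chromosome of 200000 bases were recovered with 0 wrong bases. They were built as 72 gapless bases, so this checks the computation and not the read length.

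Alignments were counted in 1 kb windows by their leftmost base and expressed as CPM, the count scaled to a library total of 1e6 alignments. The annotation at hand, GENCODE mouse release M21, is built on GRCm38, another build than that of the files, so nuclear levels are given by mm9 window with 1-based coordinates and no nuclear gene is named. Of 21 gene and marker lists fixed before the data were examined, 20 hold nuclear genes and were not analysed here. The same holds for Kdm1a, Zp3 and Xist, for coverage along transcripts, and for exon and intron shares. The exception is the mitochondrial chromosome, 16299 bases long in the files, which was taken to have the same sequence in both builds. Whether the gene positions hold was checked from depth in 5 ways, tried one after another, each against shifted placements of the genes, and the checks did not all single out the annotated place. The variance of depth between genes did not, since 19 of 161 rotations gave as much. Neither did the number of read ends at the 5' ends of genes, where 972 of 16299 placements, the annotated one included, were as high, up to 8129 bases away. Reads spanning the 5' ends were as rare at 68 placements, all within 73 bases, and were rarest 60 bases upstream of the annotation. Depth in the 22 transfer RNA genes was as low at 24 placements within 23 bases, and at 20 within 19 bases when set against local depth. The annotation was used on the strength of the last 3 checks, so gene borders are known only to within such distances. Mitochondrial alignments were assigned to a gene by their midpoint, leaving out bases that belong to more than 1 gene, and given as RPKM, the CPM per kilobase counted.

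Reads reported at several places were not foreseen in the plan, and the way to find them was chosen on the data. A total of 10 definitions were tried, namely single positions with identical counts in all libraries at 7 minimum counts, whose shuffled comparison was unsuitable, and runs of 3 positions at minimums of 10, 20 and 50 alignments. The last was kept because it recurred least in randomised counts. It takes runs of 3 neighbouring start positions with at least 50 alignments in all, whose counts in all 3 libraries and spacing occurred again elsewhere in either direction. When every count was redrawn from a Poisson distribution with its own value as the mean, 90 of 671943 runs recurred. When the positions' counts were instead permuted over the genome, 4883 of 702801 did, holding 1.07% of alignments. In a simulation with copied segments, 100% of the 3366 testable copied positions were recovered. Those copies were exact and lay on an otherwise empty sequence. The simulation thus checks the computation and says nothing about copies that differ or overlap other reads.

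Values are means with the SD over the 3 litters. With 3 litters the smallest two-sided exact sign-flip p is 0.25, so that test cannot pass 0.05 and was not run. The tests that were run set differences between the libraries against counting error. Pairs of libraries were compared by a chi-square test of window counts and by correlations of log2(CPM + 0.5) across windows, which are not independent replicates. Windows with a mean of at least 10 CPM were tested for differences between litters by a chi-square test against Poisson error with Benjamini-Hochberg adjustment at 0.05, and called varying when the highest library also exceeded the lowest over 4-fold, with counts below 3 raised to 3. On counts simulated at the means of the 10913 tested windows, this recovered 100% of windows changed 8-fold and 100% of those changed 5-fold in 1 litter, with 0 unchanged windows called. Those counts were drawn as Poisson, so the simulation says nothing about amplification noise. The test measures differences between libraries, since no litter was sequenced more than once, and a litter's biology, collection and lane are not separable. The spread of a window beyond Poisson error was estimated by the method of moments, as the variance of CPM over the litters less the Poisson part, relative to the squared mean, and no count model was fitted to these coverage tracks. The windows named are the 15 with the highest mean CPM and the 5 varying windows with the largest ratio, a rule fixed before the data were examined. The plan counted repeated alignments by start, end and strand; lacking strand, start alone was used. It also set lists against random lists of genes, which was not run on 1 chromosome. Of the mitochondrial list the rule names the 3 genes with the highest mean RPKM, and other mitochondrial genes were named after their values were seen.

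Alternatives were counting each start position once, leaving out mitochondrial and unplaced sequence, other thresholds, pseudocounts and scaling, 10 kb windows, and leaving out each litter. Leaving out recurring positions, other minimums for recurring runs and leaving out the 100 highest windows were added after seeing the data. The totals were 35183199, 31787887 and 32028802 alignments in litters 1, 2 and 3. A window with a count of 0 could then lie at up to 0.0853, 0.0944 and 0.0937 CPM, the level of 3 alignments. Intervals are 95% Wilson intervals; they and these limits cover counting error only, because no molecular identifiers are named and a read can be counted at several places. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.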

Results

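The transcriptome of ovulated mouse oocytes was profiled in 3 libraries, 1 from each of 3 litters. The design holds 1 group, so the data give the content of the oocyte RNA and its spread between litters. The libraries held 35183199, 31787887 and 32028802 alignments of 72 bases in litters 1, 2 and 3 (32999963 ± 1894571, SD, n = 3). They covered 37.1 ± 2.69 megabases, or 1.36% ± 0.0985 (SD, n = 3) of the 2726 megabases in the files. A share of 85.4% ± 0.197 (SD, n = 3) of alignments repeated the start position of another one already counted in the same library, with strands not told apart.

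The first question was how the alignments were spread over the chromosomes. A read reported at several places is counted at each, so the shares do not give the origin of the RNA. For example, 22.8% of mitochondrial alignments, as a mean over the litters, recurred on another chromosome with identical counts and spacing. Autosomes held 93.8% ± 1.81 (SD, n = 3) of alignments, the X chromosome 3.30% ± 0.598, the mitochondrial chromosome 2.06% ± 0.925 and unplaced or unlocalised sequence 0.822% ± 0.288. The X chromosome took 2.96% in litter 1 (95% Wilson interval 2.95 to 2.96), 2.94% in litter 2 (2.94 to 2.95) and 3.99% in litter 3 (3.98 to 3.99). The mitochondrial share was 1.65% in litter 1 (1.64 to 1.65), 1.41% in litter 2 (1.40 to 1.41) and 3.12% in litter 3 (3.11 to 3.12). Litter 3 thus lay above both other litters on each of these chromosomes by more than counting error. With each start position counted once, the mean mitochondrial share was 0.269%, as a chromosome of 16299 bases has few start positions.

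Windows that reached 1 CPM were spread unevenly over the nuclear chromosomes. Reads reported at several places count at each, so such a window need not be transcribed. In each litter 50632 ± 484 (SD, n = 3) windows of 1 kb reached 1 CPM, and 33083 windows did so in all 3 litters, out of 71769 that did in any. That count depends on the threshold, with 12352 windows in all litters at 5 CPM, and was 67070 at 1 CPM with each start position counted once. Chromosome 11 had the highest density, with 26.1 ± 1.07 windows at 1 CPM per megabase (SD, n = 3), followed by chromosome 19 with 24.9 ± 0.598 and chromosome 5 with 23.7 ± 0.674. The X chromosome had the lowest density of the 20 chromosomes compared, 12.1 ± 0.102, below chromosome 3 with 14.9 ± 0.387.

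A few nuclear windows held a large share of the alignments, some of them with counts that recur exactly at several places. The 15 highest windows held 19.6% ± 4.85 (SD, n = 3) of all alignments, the 100 highest 35.3% ± 6.04, and the 10000 highest 82.2% ± 0.458. The highest window of all lay on chromosome 17 (39984001 to 39985000, mm9), at 30458 ± 8943 CPM (SD, n = 3). It was followed by windows on chromosome 16 (57391001 to 57392000) at 16776 ± 4378 CPM and on chromosome 6 (145881001 to 145882000) at 15815 ± 4202 CPM. Next came windows on chromosome 2 (20821001 to 20822000) at 15718 ± 3786 CPM, chromosome 13 (44965001 to 44966000) at 15168 ± 4056 CPM and chromosome 15 (86025001 to 86026000) at 15133 ± 3655 CPM. The other 9 of the 15 ranged from 6699 ± 1307 CPM on chromosome 6 (44743001 to 44744000) to 13381 ± 3649 CPM on chromosome 12 (100883001 to 100884000). All 15 had their lowest CPM in litter 3, and the 15 together held 23.2%, 21.5% and 14.1% of alignments in litters 1, 2 and 3. The 15 are not separate observations, since 8 of them had over 50% of their alignments in recurring runs. Reads reported at several places are counted at each, in the tally and in the summed shares. With each start position counted once, the 100 highest windows held 1.55%.

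**Figure D1:**
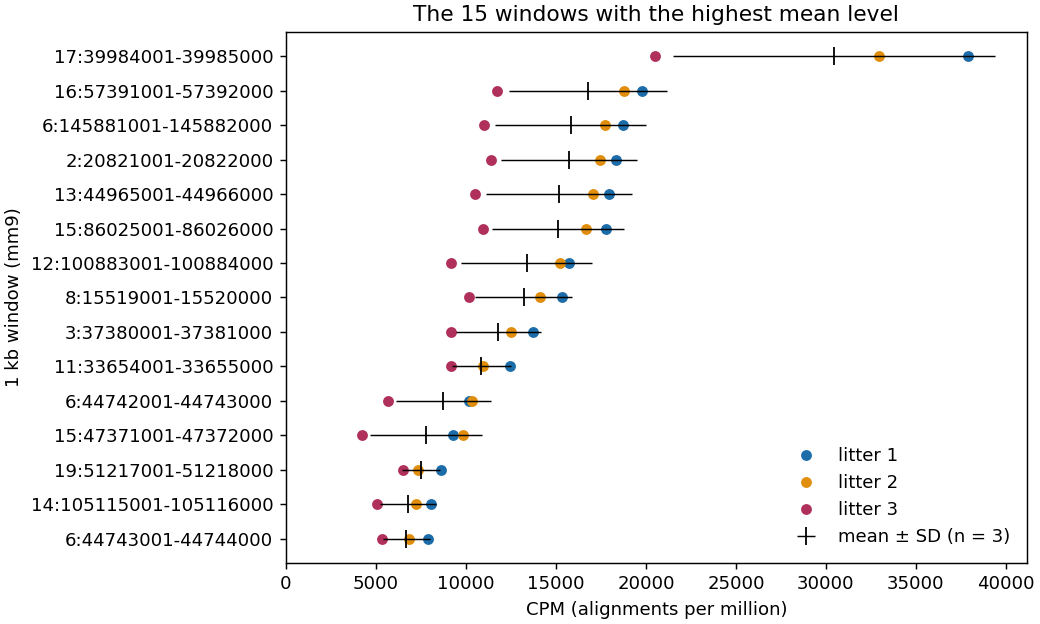
CPM (linear axis, from 0) of the 15 nuclear 1 kb windows with the highest mean level, named by mm9 chromosome, start and end. Points are the 3 litters and black bars the mean ± SD (n = 3). Litter 3 is the lowest point in all 15 windows, for example 20531 CPM against 37887 and 32954 at the highest window. Reads reported at several places are counted at each, so the 15 windows are not separate observations.

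Many counts recurred exactly at several places of the genome. The highest depth on chromosomes 2, 6, 8 and 16 was identical in every library, at 420253 alignments in litter 1, 338514 in litter 2 and 280076 in litter 3. Genome-wide, 140963 of 664866 testable runs of 3 start positions recurred elsewhere with identical counts in all 3 libraries, against 90 when counts were redrawn from Poisson distributions and 4883 when they were permuted over positions. The definition of a run was chosen on these data, and the share it gives depends on the minimum count. One run recurred at up to 19 places. Positions in recurring runs held 27.1%, 27.1% and 23.5% of alignments in litters 1, 2 and 3. Of the 15 highest windows, 8 had over 50% of their alignments in such runs, among them the windows on chromosomes 2 (98.5%) and 6 (145881001 to 145882000, 99.3%). The highest window, on chromosome 17, had 1.58%.

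The mitochondrial chromosome is the part of the data where genes could be named. The ribosomal RNA mt-Rnr1 (ENSMUSG00000064337.1, bases 70 to 1024) stood at 3127 ± 2428 RPKM (SD, n = 3), the other ribosomal RNA, mt-Rnr2 (ENSMUSG00000064339.1, bases 1094 to 2675), at 2843 ± 744 RPKM, and mt-Cytb (ENSMUSG00000064370.1, bases 14145 to 15288), the cytochrome b subunit of respiratory complex III, at 1790 ± 831 RPKM. Of these 3 genes mt-Cytb was the lowest in every litter, while mt-Rnr2 was above mt-Rnr1 in litters 1 and 2 and below it in litter 3. Both ribosomal RNAs together held 36.3% ± 2.72 (SD, n = 3) of mitochondrial alignments and the 13 messenger RNAs 59.0% ± 2.95. Another 3.80% ± 0.519 lay from base 15423 on, after the last annotated gene. The lowest levels were those of mt-Nd3, a complex I subunit, at 108 ± 15.9 RPKM, and mt-Co3, a complex IV subunit, at 193 ± 33.3 RPKM, with 79.0% and 86.5% of their alignments in recurring runs. Genes other than the first 3 were chosen after their values were seen.

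Depth dropped at the transfer RNA genes. Mean log2(depth + 1) over the 22 transfer RNA genes differed from that over the rest of the chromosome by -5.60 in litter 1, -5.93 in litter 2 and -5.18 in litter 3 (-5.57 ± 0.37, SD, n = 3). The same measure served, among 5 checks, to test the gene positions, so it is not independent of their use. The libraries carry no strand in these tracks, so reads of mt-Nd6, the 1 messenger RNA gene on the opposite strand, cannot be told from antisense reads there.

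The higher mitochondrial level of litter 3 was uneven between genes. Of the 15 genes, 12 had their highest RPKM in litter 3 and 13 their lowest in litter 2. The ratio of litter 3 to the mean of litters 1 and 2 had a median of 1.71 over the 15 genes. It was 4.57 for mt-Nd4l, a complex I subunit (767, 608 and 3144 RPKM in litters 1, 2 and 3), 3.42 for mt-Rnr1 (1933, 1526 and 5920 RPKM) and 2.70 for mt-Co1, a complex IV subunit (1199, 1026 and 3001 RPKM). It was 0.952 for mt-Nd6 and 0.874 for mt-Nd3. As shares of mitochondrial alignments, 6 genes were highest and 8 lowest in litter 3. These are single libraries per litter, so the ratios have no replicate check. Of mt-Nd4l's alignments, 99.5% lay in recurring runs, against 0% for mt-Rnr1.

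**Figure D2:**
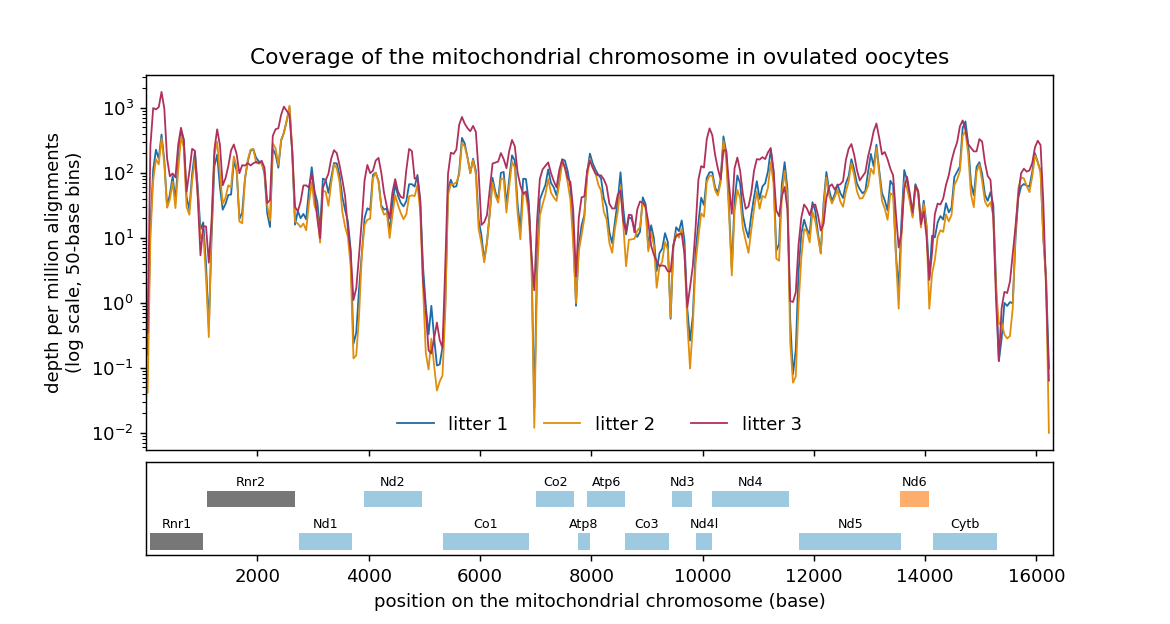
Depth scaled to 1e6 alignments (log axis, 50-base bins, empty bins drawn at 0.01) along the mitochondrial chromosome (16299 bases) in the 3 litters, above the 15 genes measured (grey, ribosomal RNA; blue and orange, messenger RNA genes of the forward and reverse strand). Depth is low at the transfer RNA genes, and litter 3 is above the other litters over the first part of mt-Rnr1 and most of mt-Co1, but not near their 3' ends.

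The last comparison was between the litters themselves. No pair of libraries differed as little as sampling noise allows: chi-square per degree of freedom over windows was 22.5 for litters 1 and 2, 88.3 for litters 1 and 3, and 92.5 for litters 2 and 3, so the 3 files were treated as separate libraries. With each start position counted once, the lowest of these values was 6.52. Across 303433 windows with any alignment, Pearson's r of log2(CPM + 0.5) was 0.91 for litters 1 and 2 (Spearman's rho 0.60), 0.86 for litters 1 and 3 (rho 0.54) and 0.85 for litters 2 and 3 (rho 0.55). Over the 52367 windows with a mean of at least 1 CPM, r was 0.86, 0.73 and 0.68 for the same pairs. The median coefficient of variation beyond Poisson error, estimated by the method of moments over the 10913 windows with a mean of at least 10 CPM, was 0.382.

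**Figure D3:**
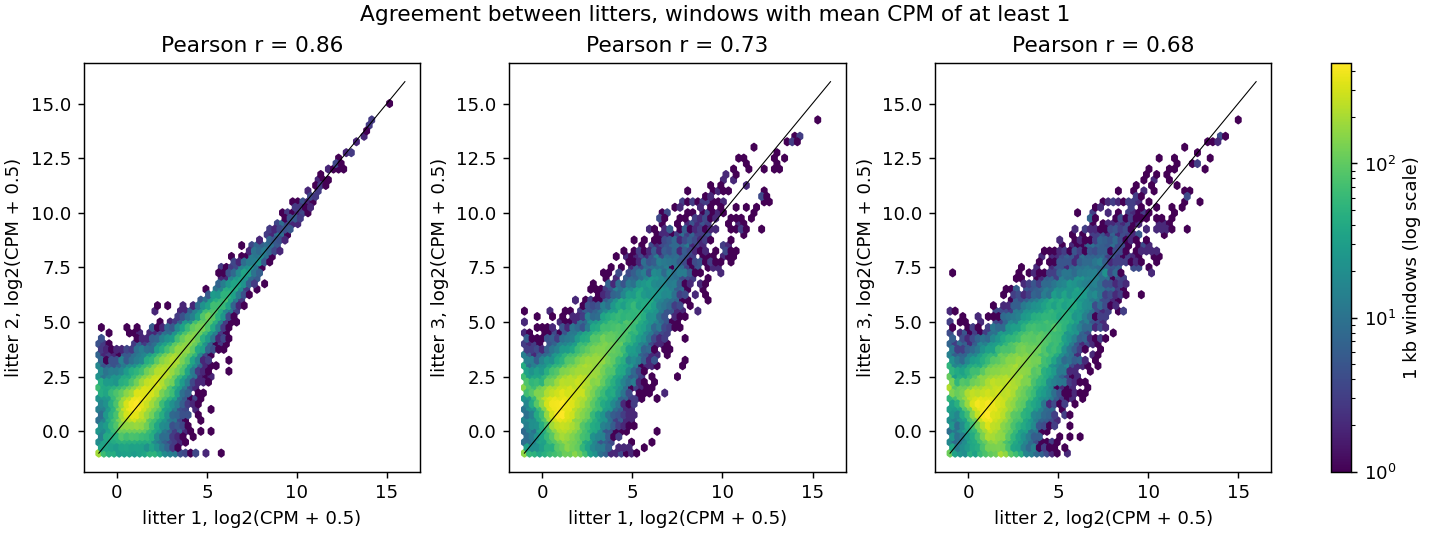
Level of each of the 52367 nuclear or mitochondrial 1 kb windows with a mean of at least 1 CPM in pairs of litters, as log2(CPM + 0.5) on both axes, with the number of windows per hexagon in colour (log scale) and the line of equal levels. Litters 1 and 2 scatter less around the line (Pearson r 0.86) than either does with litter 3 (0.73 and 0.68).

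Differences between litters reached single loci. Of the 10913 windows tested, 10637 differed between litters beyond Poisson error after Benjamini-Hochberg adjustment, and 1903 of these (17.4% of those tested) also differed over 4-fold. Poisson error leaves out amplification and reads counted at several places, so passing the adjusted test alone says little. Litter 3 was the highest or the lowest library in 1863 of the 1903. The highest was litter 1, 2 or 3 in 330, 615 and 958 windows, and the lowest in 289, 709 and 905, so the other litters were often an extreme too. The same test between litters 1 and 2 alone called 115 windows, against 1203 between litters 1 and 3 and 1691 between litters 2 and 3. With a fold limit of 2 in place of 4, 5943 windows were called. The largest ratio was on chromosome 1 (21015001 to 21016000, mm9), with counts of 1041, 0 and 4966 in litters 1, 2 and 3. On chromosome 16 (14631001 to 14632000) counts were 0, 0 and 1556, and on chromosome 9 (115021001 to 115022000) 1822, 0 and 2. On chromosome 14 (123575001 to 123576000) they were 717, 0 and 1562, and on chromosome 10 (67558001 to 67559000) 965, 1528 and 1. None of the alignments in the 5 windows with the largest ratios lay in recurring runs (0% in each).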

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

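The tests below were chosen after related values had been seen, since the share of Y alignments that recur had been looked at with a lower minimum count. Alignments appeared on the Y chromosome, which the text above does not report on its own and which the females that gave these oocytes lack. The assembled Y chromosome held 1796, 2008 and 2507 alignments in litters 1, 2 and 3, above the 3 that a count of 0 allows, or 64.2 ± 13.6 CPM (SD, n = 3). The unlocalised Y sequence, part of the unplaced or unlocalised share above, held 8397, 8525 and 11213.

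The Y signal was narrow. Of 15903 windows of 1 kb on the assembled Y chromosome, 138, 117 and 129 held any alignment, and the window from 604001 to 605000 alone held 52.8%, 53.3% and 59.8% of the Y alignments. One technical explanation is that these reads also align to other chromosomes. Of the assembled Y alignments, 50%, 50.4% and 53.8% in litters 1, 2 and 3 lay in runs deep enough to test. Of these, 58.0%, 61.4% and 40.3%, or 51.7% in all, recurred on another sequence with identical counts and spacing. That lies between the 80% set as needed and the 20% set as excluding it. The assembled and the unlocalised Y are separate sequences in the files, so copies between them count here too. On the unlocalised Y sequence the share was 88.7%, past the 80%, although 27.8%, 28.7% and 55.8% of its alignments in litters 1, 2 and 3 could be tested. Reads with copies on another sequence may therefore account for most of the testable unlocalised signal and part of the rest. Copies shared only between the assembled and the unlocalised Y were not told apart, so an origin outside the Y is not shown. Similar sequence with mismatches, RNA of male cells and strain differences from the reference stay open, and no biological explanation was tested.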

How the results depend on the processing

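Of 66 alternatives, 45 left the result within the spread between litters, for counts within 1.5 times, or, for the comparison of library pairs, past the threshold of its test. Where a result is a mean over the litters, leaving out a litter cannot move it past that spread. Such alternatives are among the 45 and were no check. Leaving out recurring positions, leaving out the 100 highest windows and other minimums for recurring runs were chosen after seeing the data. Leaving out recurring positions lowered the mean depth to 24442939 alignments and the share in the 100 highest windows to 27.7%. The share of alignments in recurring runs, 25.9% with at least 50 alignments per run, was 28.5% at 20 and 35.3% at 10, where Poisson-redrawn counts gave 1.01% and 8.24% and permuted positions 3.68% and 12.5%. Counting each start position once, which caps every base at 1 alignment, lowered the mean depth to 4801237 alignments, the mitochondrial share to 0.269%, the share in the 100 highest windows to 1.55%, the median log2 RPKM of the mitochondrial genes from 9.86 to 7.51, the mean Pearson r from 0.87 to 0.79 and the lowest chi-square per degree of freedom of a pair from 22.5 to 6.52, and raised the X share to 4.21% and the windows at 1 CPM in all litters to 67070. That count was 117796 at a threshold of 1 alignment and 12352 at 5 CPM. Mean r was 0.75 over windows with at least 1 CPM and 0.91 with a pseudocount of 5. The varying windows numbered 5943 with a fold limit of 2 and 18397 with a mean of at least 1 CPM. Without mitochondrial and unplaced sequence, 85.2% of alignments repeated a start. Leaving out each litter gave a mean r of 0.85 to 0.91 and 115 to 1691 varying windows, the lowest without litter 3 and 1203 without litter 2. Beyond the alternatives' own construction, the cause was not tested. Within these limits stayed the share in the 100 highest windows with 10 kb windows, the varying windows and mitochondrial median with median-of-ratios scaling, and that median with a pseudocount of 1. No paired analysis was possible because the series holds 1 group. Not run were the alternatives for marker lists, Kdm1a exons, transcript coverage, exon and intron shares, and the protein-coding background, which need an mm9 annotation. Depth limits the windows at a count of 0 or near it.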

Other observations

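The tests of neighbouring windows and leaving out recurring positions were chosen after the data were seen.

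Counts on the mitochondrial chromosome recurred at a few nuclear places. A share of 22.8% ± 1.86 (SD, n = 3) of mitochondrial alignments recurred on another chromosome with identical counts and spacing. Runs of 3 start positions that also occur on the mitochondrial chromosome numbered 3262 elsewhere, against 10 when counts were permuted over positions and 0 when they were redrawn. On chromosome 1, 1721 of them lay within bases 24620001 to 24630000 and 884 within 24610001 to 24620000. Chromosome 2 held 336 (22440001 to 22450000) and chromosome 12 held 204 (98290001 to 98300000). Within the mitochondrial genes, 99.4% of mt-Co2 and 98.5% of mt-Atp6 alignments lay in recurring runs, against 0% in mt-Nd1, mt-Nd6 and mt-Cytb.

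The stretch with the most varying windows, 6, was nearly absent from litter 3. On chromosome 10, these windows between 67556001 and 67565000 held 6598 and 6821 alignments in litters 1 and 2 and 34 in litter 3. On chromosome 6, 4 windows between 149273001 and 149284000 held 3158, 2015 and 10307. Neither stretch had alignments in recurring runs (0% in each), and both were chosen after their values were seen.

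Noticed in the list of varying windows before it was tested, the hypothesis is that litters differ along whole transcribed loci, not window by window. Among 180 pairs of varying windows at most 5 kb apart, 75.6% shared their highest litter, above the 47.8% that was the highest of 100 permutations. This argues against windows that vary independently of their neighbours. It does not show that whole transcribed loci differ, because neighbouring windows can divide a single stretch of coverage and no nuclear locus was annotated. The list tested is also the list that prompted the hypothesis. Among the 117 such pairs of windows without alignments in recurring runs the share was 70.9%, above the 47.0% that was the highest of 100 permutations. Loci found to recur are thus not the whole cause. Copies outside testable runs could not be found and stay in, so loci counted repeatedly are not excluded. Most of the 1903 varying windows still stood alone, since 1570 of the 1723 loci they form held a single window.

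Litter 3 stood apart from the other litters. In windows with a mean of at least 10 CPM, the SD of log2 ratios was 0.60 for litters 1 and 2 but 1.24 and 1.37 for the pairs with litter 3, whose mean is 2.17 times the former. With recurring positions left out the ratio was 1.99, so the positions found to recur are not the whole cause. Testable runs held 77.7%, 77.4% and 73.9% of alignments in litters 1, 2 and 3. Reads placed at several positions outside such runs stay in, so that explanation is not excluded. Among the 6752 windows with at least 200 start positions the ratio was 2.00. That filter does not limit how many alignments share a start, so it cannot decide whether single fragments copied many times are the cause. Differences in the animals, in collection or amplification, and in the lane stay open and cannot be told apart, because each litter has 1 library from its own lane.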
